A study of Mus musculus with 4 samples.

How the data were processed

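The 4 libraries were made from total RNA of stem cell derived motor neuron cultures with the Illumina TruSeq protocol and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name CASAVA, TopHat2, HTSeq and DESeq and the genome build mm9, without versions or settings, and these tools carry no role or order there. The deposited table holds a signal per gene, a normalized read count with 2 decimals that the authors obtained by dividing gene counts by 1 size factor per library, as far as the values show. In each column 100% of the values lie within 0.1 of a whole multiple of 1 step (0.894, 1.07, 1.18 and 0.882 normalized counts in libraries 1, 7, 2 and 8), which was read as the value of 1 read. Too few values lie near the step to treat the multiples as recovered reads, so no count model was fitted, and read numbers are given as estimates. Each row has at least 101 estimated reads in 1 or more libraries, so genes with fewer reads are not listed, and a gene that is not listed cannot be called absent.

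Column names carry the initials of the treatment label and a number. The initials gave each column its group, and the numbers (1 and 7 without, 2 and 8 with doxycycline) are not the replicate numbers of the labels, so columns were not matched to single samples. Libraries of a group were compared by a chi-square test on estimated reads. The chi-square per degree of freedom was 26.4 between libraries 1 and 7 and 28.3 between 2 and 8, so neither pair was 1 library listed more than once. Rows are RefSeq accessions, and 2938 of the rows join several. A symbol was given in the table for 11335 rows and taken by accession from a RefSeq table on GRCm38 for 377, while 28 rows name several genes and 7 have no symbol. That annotation served for names and for the order of neighbouring genes only, and no coordinates are given, since its build differs from mm9. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart, and ribosomal protein genes, which have many near-identical pseudogene copies, are uncertain one by one.

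Values were analysed as log2(normalized count + 1) with the authors' scaling kept. The planned filter, a mean of at least 10, removed no row, since the lowest row mean was 40.1. Group differences were tested for 11747 rows with limma 3.58.1 in R 4.3.3, using moderated tests with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual and 3.83 prior degrees of freedom, and the median standard error was 0.098 on the log2 scale. For single genes an exact permutation test of 2 against 2 libraries cannot go below p = 0.333. For genes with few reads without doxycycline the ratio of estimated reads per library size is given with an exact Clopper-Pearson 95% interval, which covers counting error only.

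The 33 gene lists, with 495 genes, the tests and the rule for named genes were fixed before the data were examined. The rule takes the induced gene, the 10 largest rises and 10 largest falls among genes past the test with a mean of at least 50, no overlap between groups and a symbol that is not a clone or predicted gene number, a fixed panel, and up to 4 members of each list with the smallest p. It names 127 genes, of which some, the induced gene included, are not reported here; other genes in the text were chosen after their values were seen, as members of a list or as examples. The 25 lists with at least 5 listed members were tested with limma's camera at a preset correlation of 0.01 against all other genes, adjusted over lists. Camera with an estimated correlation, camera on ranks and fry, directional and mixed, were alternatives. The estimated correlation comes from the 2 residual degrees of freedom, so that version has little power here. Fry asks whether a list's genes move at all and does not compare them with other genes.

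Other alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, quantile normalization, TMM factors written from their definition (trims of 0.3 and 0.05), robust empirical Bayes, no trend, a log2 change of at least 1, and each library left out in turn. The pairing of libraries 1 with 2 and 7 with 8 was added after the data were seen. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9. The limma step was tested on simulated data, 5 sets of 11747 genes with the real means and library sizes and 200 changed genes. It called 70% of genes changed 1.25-fold, 96.4% at 1.5-fold and 100% at 2-fold and 4-fold, with a mean of 10.2 unchanged genes called. The simulated dispersion was a single value, 0.00156, for all genes. In the real fit the spread varied from gene to gene, with 3.83 prior degrees of freedom. These shares therefore do not carry over to the real libraries and are likely too high for them. The 10 most abundant rows held 4.14% to 5.20% of a library's normalized counts.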

Results

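Gene expression was measured by RNA sequencing in 4 libraries of motor neuron cultures made from mouse embryonic stem cells. The cells derive from the A172LoxP line and were engineered so that doxycycline, an antibiotic used as a chemical switch, turns on a transgene that encodes a transcription factor. Embryoid bodies, floating aggregates of the cells, were patterned for 2 days with 0.5 µM retinoic acid and 1 µM purmorphamine, an agonist of Sonic hedgehog signalling. They were then kept for a further 2 to 3 days with 2 µg/mL doxycycline or with vehicle. There were 2 libraries per group. The libraries without doxycycline carry the numbers 1 and 7 in the deposited table, and those with doxycycline the numbers 2 and 8. The table lists 11747 genes or gene groups, with normalized read counts that sum to between 26449555 and 27047458 per library. The reads behind them were estimated at 29905678 in library 1, 25190896 in library 7, 22434755 in library 2 and 30235763 in library 8. Nothing in the labels says that the libraries of a group came from separate cultures. The p-values of single genes therefore measure the spread between these libraries, which may be technical. Camera at its preset correlation compares a list with all other genes, so its p-values rest mainly on the spread across genes. Values below are means ± SD of normalized read counts over n = 2 libraries per group. Fold changes are log2 differences of normalized count + 1, given ± SE, which understates the change of genes with few reads.

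The comparison of cultures with and without doxycycline asks which genes respond to the induced factor. Doxycycline was followed by more falls than rises. Of the 11747 genes tested, 278 passed the limma test, 68 of them higher and 210 lower with doxycycline. Among these, 21 rose and 77 fell at least 2-fold, and 9 rose and 12 fell at least 4-fold. The median change was 0.74 among the genes that rose and -0.86 among those that fell. At an unadjusted p under 0.05, 2474 genes differed. In all 278 genes both libraries of one group lay above both of the other. Over all genes this held for 53.2%, where chance gives 33.3%. With the groups apart, leaving out 1 library could not change the direction of any of the 278 genes. The number of calls changed with the library left out. Each such fit has 1 library in 1 group, so a lost call need not mean that the change rests on that library alone. Libraries 1 and 2 also differed from 7 and 8 in many genes, so such a fit is unbalanced. A list call gained in it cannot be told apart from that difference. Leaving out library 1, 7, 2 or 8 gave 133, 494, 113 and 44 calls, of which 122, 241, 98 and 42 were among the 278, and all 278 kept their direction each time.

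**Figure D1:**
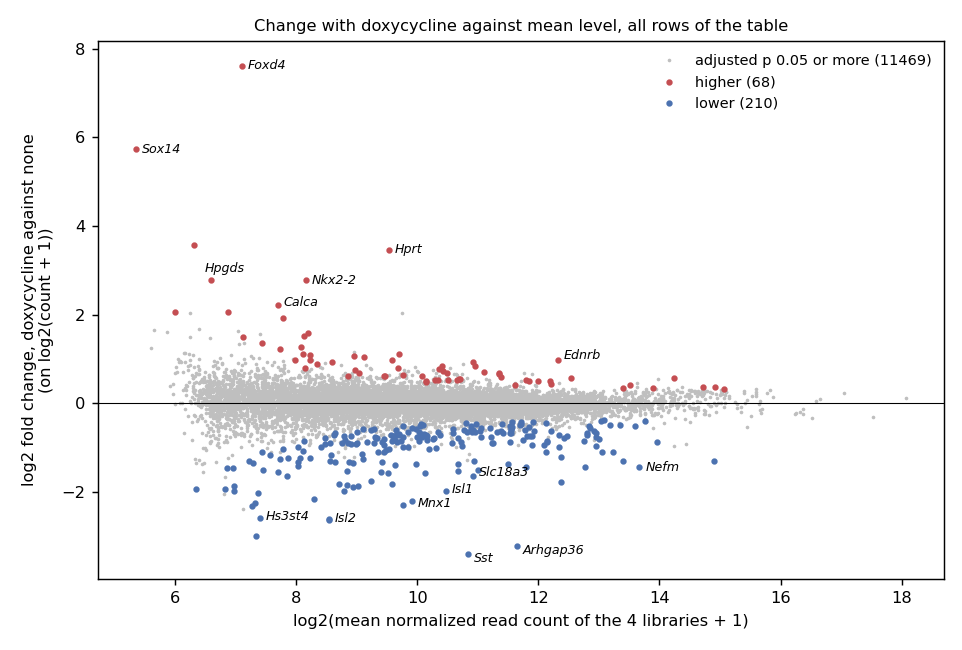
Change with doxycycline (y axis, log2 fold change on normalized count + 1) against the mean level over the 4 libraries (x axis, log2), with each point a row of the table. Red points mark the 68 genes that rose, blue points the 210 that fell and grey points the rest; Foxd4 lies highest at 7.62 and Sst lowest at -3.41.

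The largest rise among genes with a mean of at least 50 was that of Foxd4, a forkhead transcription factor, by 7.62 ± 0.64 (limma, adjusted p = 0.0105). It was listed at 0.445 ± 0.629 normalized counts without and 273 ± 67.8 with doxycycline. This corresponds to 1 against 555 estimated reads, a ratio of 574 with a 95% counting interval of 103 to 22720. Hprt, the enzyme of purine salvage, rose from 121 ± 22.6 to 1354 ± 281, a log2 change of 3.46 ± 0.20 (limma, adjusted p = 0.00661). Hpgds, a prostaglandin D synthase, rose by 2.78 ± 0.36. Nkx2-2, a homeodomain factor of the most ventral neural progenitors, rose from 72.5 ± 28.0 to 498 ± 163. Calca, which encodes calcitonin and calcitonin gene-related peptide, rose by 2.22 ± 0.30. The rise was 2.06 ± 0.32 for Calb2, which encodes calretinin, 2.05 ± 0.24 for Pcp4, 1.93 ± 0.26 for Pmfbp1 and 1.60 ± 0.13 for the neuropeptide gene Cartpt. Of these 9 genes, Hprt alone stayed past the limma test whichever library was left out. Without library 8 the other calls were lost. Those of Foxd4, Hpgds, Calb2, Pcp4 and Pmfbp1 were also lost without library 2, and that of Calb2 without library 1 or 7.

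The largest fall was that of Sst, which encodes the neuropeptide somatostatin, from 3355 ± 609 to 315.5 ± 65.7 normalized counts, a change of -3.41 ± 0.18 (limma, adjusted p = 0.00661). Arhgap36 decreased by 3.23 ± 0.22, from 5765 ± 330.0 to 630.2 ± 213. Falls of over 4-fold were also measured for the motor neuron transcription factors Isl2 (-2.60 ± 0.27) and Mnx1 (-2.21 ± 0.16) and for the LIM-only factor Lmo1 (-2.02 ± 0.29). The heparan sulfate sulfotransferase gene Hs3st4 changed by -2.59 ± 0.19, the zinc finger gene Prdm16 by -2.33 ± 0.24 and the exchange factor gene Rasgef1c by -2.29 ± 0.10. Tmem132d changed by -2.25 ± 0.25 and Angpt1, a growth factor of blood vessels, by -2.16 ± 0.30. Among these 10 genes the calls of Tmem132d, Angpt1 and Lmo1 were lost without library 8, and that of Lmo1 also without library 1.

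Genes of the V2 lineage moved in both directions. Of the 8 listed members of the V2a and V2 list 3 rose, Sox14 and Sox21 among them, and 1, Lhx4, fell. These counts include 1 member that is not reported here and is no independent evidence for the list. Sox14, a transcription factor of V2a interneurons, was listed at 0 and 1.07 normalized counts without and at 54.2 and 105 with doxycycline. That corresponds to 1 against 165 estimated reads, a ratio of 171 with a 95% counting interval of 30.2 to 6783 (limma, adjusted p = 0.0458). Sox21 rose from 517 ± 64.8 to 1016 ± 161. The LIM-homeodomain factor Lhx4 decreased by 0.92 ± 0.15. Lhx3, a LIM-homeodomain partner shared by V2a interneurons and motor neurons, had a value of 0.55 ± 0.17 that did not pass (limma, adjusted p = 0.155). Adjusted over the list alone, 4 members rose and 2 fell. The list as a whole was not called by camera (limma, adjusted p = 0.128; adjusted p = 0.634 with an estimated correlation). Less that member, an alternative chosen after the data were seen, the list's 7 genes had a median of 0.55 and were not called either (limma, adjusted p = 0.418; adjusted p = 0.674 with an estimated correlation). Camera called the list higher without library 1 (limma, adjusted p = 0.00212, and 0.0248 less that member), but not without library 7, 2 or 8 less that member (adjusted p = 0.731, 0.927 and 0.292). The calls of Sox14 and Sox21 were lost without library 2 or 8, that of Sox21 also without library 1, and that of Lhx4 without library 1 or 8.

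Several motor neuron genes fell. Of the 20 listed motor neuron transcription factors, 7 fell and none rose over all genes, and 7 fell and 1 rose adjusted over the list alone. The 7 were Isl2, Mnx1, Lmo1, Isl1, Ebf2, Lhx4 and Etv5. Isl1, a LIM-homeodomain factor of motor and sensory neurons, fell from 2257 ± 105 to 588 ± 214. The list had a median change of -0.34 and was called lower by camera (limma, adjusted p = 0.00111; adjusted p = 0.634 with an estimated correlation). The estimated correlation left none of the 25 tested lists called. That version rests on the 2 residual degrees of freedom, so a list that it leaves uncalled is not shown to be unchanged. Olig2, the transcription factor of motor neuron progenitors, was at 2663 ± 243 without and 3025 ± 190 with doxycycline, and did not pass (limma, adjusted p = 0.311). Of the 14 listed cholinergic and motor neuron effector genes, 8 fell and 1, Calca, rose. Slc18a3, the vesicular acetylcholine transporter, fell from 2920 ± 76.7 to 941 ± 58.2 and Chat, which makes acetylcholine, from 776 ± 14.8 to 327 ± 55.1. The intermediate filament gene Prph changed by -1.57 ± 0.11, the neurotrophic factor receptor gene Ret by -1.51 ± 0.10 and the adhesion gene Cadm1 by -1.11 ± 0.07. Adjusted over the list alone, 9 fell and 1 rose. The list's median was -1.11 and camera called it lower (limma, adjusted p = 6.67e-08; adjusted p = 0.634 with an estimated correlation). Without library 8 the calls of Chat, Slc10a4, Ngfr, Calca, Lmo1, Ebf2, Lhx4 and Etv5 were lost, those of Lmo1, Ebf2, Lhx4 and Etv5 also without library 1, and that of Etv5 without library 2 or 7 as well, while those of Mnx1, Isl1, Isl2, Slc18a3, Prph, Ret, Nrg1 and Cadm1 stood without any single library.

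**Figure D2:**
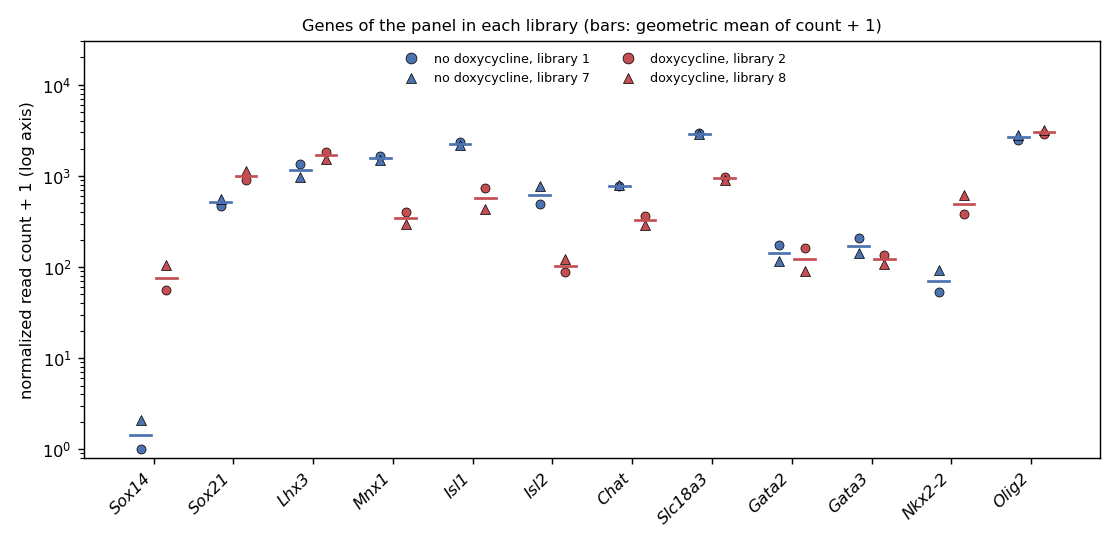
Normalized read count + 1 (log axis) of panel genes chosen before the data were examined, in each of the 4 libraries, with bars at the geometric mean of each group. Sox14 and Nkx2-2 lie higher in both doxycycline libraries (red), Mnx1, Isl1, Isl2, Chat and Slc18a3 lie lower, and Gata2 and Olig2 differ by less than 0.25 on the log2 scale.

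Genes shared by most neurons fell as well. All 20 listed pan-neuronal genes had values below 0, and 13 of them fell (19 adjusted over the list alone), with a median of -0.84. The neurofilament gene Nefm decreased by 1.45 ± 0.10, the growth cone gene Gap43 by 1.43 ± 0.11, the microtubule regulator gene Stmn2 by 1.09 ± 0.10 and Mapt, which encodes tau, by 0.83 ± 0.08. Camera called the list lower (limma, adjusted p = 4.24e-18; adjusted p = 0.634 with an estimated correlation). Of the 14 listed potassium, sodium and calcium channel genes, Scn3b (-0.72 ± 0.09) and Cacna1g (-1.03 ± 0.16) fell, and 8 fell adjusted over the list alone. That list had a median of -0.44 (camera in limma, adjusted p = 2.85e-05; adjusted p = 0.634 with an estimated correlation). Of the 30 listed axon guidance and adhesion genes, 5 fell and none rose. They were Slit2 (-1.30 ± 0.16), Slit3, L1cam (-0.94 ± 0.11), Ephb1 and Nrp2. Adjusted over the list alone, 11 fell and 3 rose, and camera did not call the list (limma, adjusted p = 0.124; adjusted p = 0.634 with an estimated correlation), but called it lower without library 1 (adjusted p = 0.0102) or 2 (adjusted p = 0.0229). Of the 13 pan-neuronal calls 6 stood without any single library, those of Elavl2, Stmn2, Gap43, Nefl, Nefm and Ina. The other 7, Elavl3, Elavl4, Mapt, Snap25, Dcx, Syn1 and Sncg, were lost without library 8, with 4 of them also lost without library 1 and 4 without library 2. Without library 8 the calls of Scn3b, Cacna1g, Slit3, Ephb1, L1cam and Nrp2 were lost. Those of Scn3b, Cacna1g, Ephb1 and Nrp2 were also lost without library 2, and those of Scn3b and Ephb1 without library 1.

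Lists of proliferation and signalling genes had medians above 0. Of the 25 cell cycle genes none passed the test over all genes and 3 rose adjusted over the list alone, while 23 had values above 0, with a median of 0.19. The mitotic genes Bub1 (0.35 ± 0.08) and Ccnb1 (0.32 ± 0.07) and the topoisomerase gene Top2a (0.34 ± 0.09) are examples. Camera called the list higher (limma, adjusted p = 1.58e-05; adjusted p = 0.634 with an estimated correlation). Of the 12 listed Sonic hedgehog response genes, 11 had values above 0, and Nkx2-2 alone rose over all genes and 4 rose adjusted over the list alone. Gli1, a target and effector of the pathway, had a value of 0.52 ± 0.10 and the co-receptor gene Boc one of 0.59 ± 0.11. The list's median was 0.31 (camera in limma, adjusted p = 0.00105; adjusted p = 0.634 with an estimated correlation). Of the 18 Notch pathway genes 12 had values above 0 and 6 below, Notch3 rose by 0.43 ± 0.07, and 2 rose adjusted over the list alone, with a median of 0.20 (camera in limma, adjusted p = 0.00641; adjusted p = 0.634 with an estimated correlation). The call of Notch3 was lost whichever library was left out. Of the 14 listed hypoxia and glycolysis genes none passed over all genes and 3 rose adjusted over the list alone. The median of that list was 0.34 (camera in limma, adjusted p = 0.00122; adjusted p = 0.634 with an estimated correlation), but 0.10 without library 1.

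**Figure D3:**
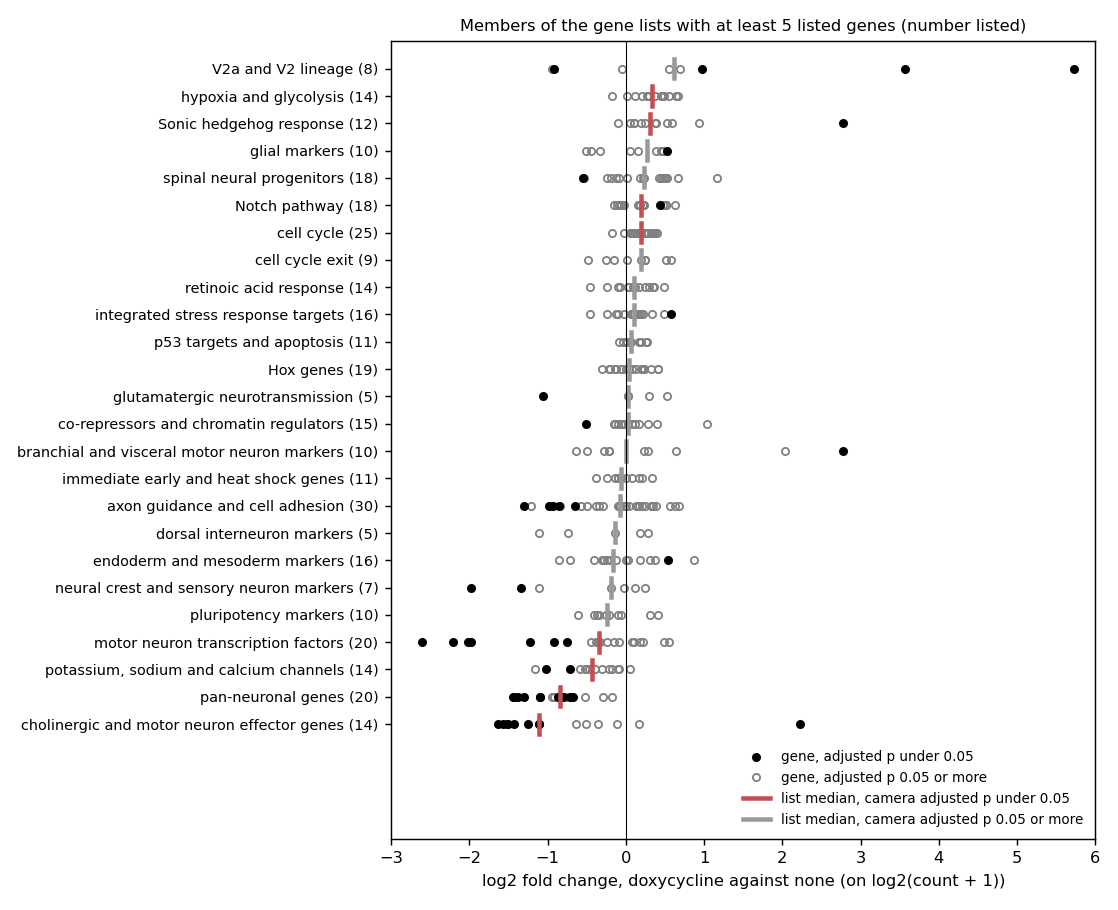
Log2 fold change with doxycycline (x axis, on normalized count + 1) of each listed member of the 25 gene lists with at least 5 listed genes (y axis, number listed in brackets). Filled points are genes with an adjusted p under 0.05, and bars are list medians, in red where camera called the list; the lowest median is -1.11, for cholinergic and motor neuron effector genes, and the highest 0.62, for the V2a and V2 list.

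Markers of other spinal neurons were few in the table. Gata2 (-0.22 ± 0.34) and Gata3 (-0.50 ± 0.25), factors of V2b interneurons, did not pass the test, and neither did Sox1 (0.50 ± 0.10), the remaining listed gene of that list. Adjusted over the list alone, 1 of these 3 rose. Of 3 listed V3 genes Nkx2-2 rose, while Nkx2-9 (2.04 ± 0.48) and Pou2f2 (-0.34 ± 0.10) did not pass. Adjusted over the list alone, 2 of those rose and 1 fell. None of the 4 listed V1 genes passed over all genes (2 fell adjusted over the list alone), nor did either of the 2 listed V0 genes (1 fell adjusted over the list alone), and Lhx1, in both lists, had a value of -0.97 ± 0.19. Of the 10 branchial and visceral motor neuron markers Nkx2-2 alone rose, and 2 rose adjusted over the list alone. None of the 5 listed dorsal interneuron markers passed over all genes, and 1 fell adjusted over the list alone. Neither list was called by camera (limma, adjusted p = 0.485 for each; adjusted p = 0.674 with an estimated correlation). Of 5 glutamatergic genes the receptor gene Gria2 fell by 1.05 ± 0.11, over all genes and adjusted over the list alone, and the list was not called (camera in limma, adjusted p = 0.911; adjusted p = 0.920 with an estimated correlation). Its call was lost without library 2 or 8. None of the 3 listed GABAergic and glycinergic genes passed in either way. The panel genes Slc5a7, Vsx1, Shox2, Slc17a6, Tal1, En1, Evx1 and Sim1 were not listed in the table.

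In the main fit the lists of progenitors and of other cell types were not called by camera. With libraries paired by column number, an alternative added after the data were seen, camera called the progenitor and neural crest lists. Of 18 spinal progenitor genes, Irx3 fell (-0.55 ± 0.09), and 7 rose and 2 fell adjusted over the list alone (camera in limma, adjusted p = 0.124; adjusted p = 0.634 with an estimated correlation). Of 10 glial markers the glutamate transporter gene Slc1a3 rose by 0.52 ± 0.08 (1 rose and 1 fell adjusted over the list alone; camera in limma, adjusted p = 0.321). Of 7 neural crest and sensory neuron markers 2 fell, Isl1 among them, and 2 fell adjusted over the list alone (camera in limma, adjusted p = 0.124). Of 16 endoderm and mesoderm markers the lipoprotein gene Apoe rose by 0.54 ± 0.08, with 1 rise and 2 falls adjusted over the list alone (camera in limma, adjusted p = 0.764). The mean log2 level of that list was 9.31 and 9.62 in libraries 1 and 7, and 9.22 and 9.57 in libraries 2 and 8. None of the 10 pluripotency markers passed in either way (camera in limma, adjusted p = 0.513). With an estimated correlation the adjusted p was 0.634 for glial, 0.698 for neural crest, 0.917 for endoderm and mesoderm and 0.815 for pluripotency markers in limma. The 1 listed retinal gene, Prkca (-0.33 ± 0.13), and the 1 listed forebrain and midbrain gene, Neurod1 (0.24 ± 0.15), did not pass over all genes, and Prkca fell adjusted over the list alone. Camera called the progenitor list higher without library 7 (limma, adjusted p = 0.0195) or 2 (adjusted p = 0.0229), and the neural crest list lower without library 7 (adjusted p = 0.00631) or 2 (adjusted p = 0.00351). Without library 8, 2 or 1 the calls of Irx3, Slc1a3 and Apoe were lost, and that of Slc1a3 also without library 7.

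Patterning and stress lists were not called with all 4 libraries. None of the 19 Hox genes, 14 retinoic acid response genes, 9 cell cycle exit genes, 11 immediate early and heat shock genes or 11 p53 targets passed the test over all genes or adjusted over the list alone. Their medians were 0.04, 0.10, 0.19, -0.06 and 0.07. Camera gave adjusted p = 0.668, 0.321, 0.676, 0.676 and 0.183 in limma, and 0.917, 0.634, 0.815, 0.815 and 0.815 as adjusted p with an estimated correlation. Hoxd3, with the smallest p of the Hox genes, had a value of 0.41 ± 0.12. The other listed Hox genes were lower in library 7 than in 1 and in library 8 than in 2. Fits with 1 library left out are therefore unbalanced for this list, and the same split can unbalance them for the other lists. Camera called the Hox list higher without library 1 (limma, adjusted p = 5.58e-05) or 8 (adjusted p = 0.0279), and lower without library 7 (adjusted p = 0.0269). Without library 1 it also called higher the retinoic acid list (limma, adjusted p = 0.0270), the p53 list (adjusted p = 0.000831) and the stress response targets (adjusted p = 0.0435). The p53 list was called without library 8 as well (limma, adjusted p = 0.0126). Of 16 integrated stress response targets Phgdh, of serine synthesis, rose by 0.58 ± 0.08, and 2 rose adjusted over the list alone (camera in limma, adjusted p = 0.124; adjusted p = 0.634 with an estimated correlation). Of 15 co-repressor and chromatin genes the co-repressor gene Tle4 fell by 0.51 ± 0.07, with 1 rise and 1 fall adjusted over the list alone (camera in limma, adjusted p = 0.764; adjusted p = 0.907 with an estimated correlation). The calls of Phgdh and Tle4 were lost without library 1, 2 or 8. None of the 13 mitochondrially encoded transcripts was listed in the table. Directional fry called none of the 25 tested lists (limma, lowest adjusted p = 0.0806), and its mixed test, for change in either direction, called 15.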

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

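The pairing and the V2 list less 1 member were chosen after the data were seen, and the other settings here were planned. For called genes, leaving out 1 library could not reverse the direction, since the groups did not overlap. The 278 calls became 277 and 280 with pseudocounts of 0.5 and 5, 278 with no filter, 278 with a mean of at least 50, 275 with TMM factors and 222 with quantile normalization. Robust empirical Bayes gave 419 calls (132 higher), no trend 105 (27 higher, 78 lower), and a log2 change of at least 1 left 98 (21 higher, 77 lower) by construction. With 1 library left out, and the lone library assumed to vary like the other group, calls ranged from 44 (without library 8) to 494 (without library 7), with 2 to 156 higher and 42 to 338 lower. Of the 124 named genes reported here, of 127 in all, none reversed; 21 calls were lost with no trend, 3 with quantile normalization, and 12, 3, 18 and 28 without libraries 1, 7, 2 and 8, where 7, 1, 3 and 5 uncalled genes changed sign. The 8 list calls became 0 with an estimated correlation, 0 with fry and 15 with fry's mixed test (5 of the 8 among them), and 10 to 14 with 1 library left out, when all 8 remained. Without library 7 the Hox list was called in the opposite direction (limma camera, adjusted p = 0.0269), and over all fits with 1 library left out its adjusted p was 5.58e-05 (without library 1) to 0.489 (without library 2). All listed Hox genes except Hoxd3 were lower in library 7 than in 1 and in library 8 than in 2, while Hoxd3 was higher in 8. Leaving out 1 library breaks that balance, so the direction of these Hox calls cannot be read as a response to doxycycline. Other causes were not tested.

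As a replicate block, the pairing of consecutive column numbers gave 3508 calls (1636 higher, 1872 lower) with all 278 among them, and 11 called lists. These were the 8 lists of the main fit and the spinal progenitor, axon guidance and neural crest lists (limma camera, adjusted p = 0.00319, 2.4e-05 and 6.23e-07). Deviations of libraries 1 with 2 and 7 with 8 from their group means correlated across genes (r = 0.63, rho = 0.47), but nothing in the labels pairs them. That fit has 1 residual degree of freedom and an infinite prior, so its p-values rest on 1 trend for the spread of all genes. The count tests of edgeR and DESeq2 were not run, since recovered reads were not accepted for this table. The block by the labels' replicate numbers was not run, since the columns do not carry them. The deposited table lists only genes with over 100 estimated reads in at least 1 library, so genes below that were not analysed here.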

Other observations

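Of the tests in this part, those on the share and mixture of neurons, on library 1 and on the stress response were chosen after the result was seen, as were the genes and families named in the next paragraphs; those on Hprt were written before. Genes outside the fixed lists that rose with doxycycline include several examples picked by their values. The endothelin receptor gene Ednrb rose by 0.97 ± 0.06, from 3454 to 6788 normalized counts (limma, adjusted p = 0.00661), and stayed past the test without any single library. The transcription factor gene Pou3f2 rose by 0.84 ± 0.07, Sall3 by 0.93 ± 0.12, the signalling gene Wnt7a by 1.07 ± 0.18, Cspg5 by 1.03 ± 0.12 and the receptor gene Fgfr3 by 0.68 ± 0.11, and each of these calls was lost in at least 1 fit with a library left out. Of 78 listed ribosomal protein genes, 77 had values above 0 and 5 passed the test, with a median of 0.24. With quantile normalization 76 and with TMM factors 77 were above 0. The median was 0.27 between libraries 2 and 1 and 0.21 between 8 and 7. Among the falls outside the naming rule, 9430031J16Rik changed by -2.99 ± 0.27 and 3110047P20Rik by -2.64 ± 0.20, each with an adjusted p (0.0136 and 0.00962, limma) that stayed under 0.05 without any single library.

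A second structure cut across the treatment. The first principal component, 64.0% of the variance, separated the libraries by doxycycline, and the second, 29.0%, separated libraries 1 and 2 from 7 and 8. Of the 16 listed endoderm and mesoderm markers 11 were higher and 3 lower in both 7 against 1 and 8 against 2, and of the 10 listed pluripotency markers 2 were higher and 8 lower. No test of this split was made. Among examples picked for their differences, Col4a1 was listed at 132457 and 96510 normalized counts in libraries 1 and 2 and at 276654 and 246997 in libraries 7 and 8, and Nid1, Sparc, Lama1, Gata4, Gata6, Dab2 and Sox17 differed in the same direction in both pairs. Pou5f1, Dppa5a, Tdh, Folr1 and H19 were lower in libraries 7 and 8. H19 was listed at 769 and 706 in libraries 1 and 2 and at 179 and 174 in libraries 7 and 8. None of these genes passed the limma test for doxycycline. They were picked for differences between libraries of a group, which raise the standard error, so this does not show a lack of response. In all, 33 genes were at least 2-fold higher and 20 at least 2-fold lower in both 7 against 1 and 8 against 2, beside 30 higher and 87 lower in both 2 against 1 and 8 against 7. The ribosomal RNA precursor NR_046233 stood at 27547 in library 1 and between 10206 and 12719 in the other libraries.

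Hprt rose by 3.46 ± 0.20, while the other listed genes of its pathway did not pass the test. If transcription ran on from an induced cassette into every gene near Hprt, the closest listed genes would rise, but the higher of both values was -0.18, for Phf6, with Fam122b at -0.34 on the other side. A change of purine metabolism as a whole was argued against as the source of a rise of that size. The median of 17 other purine genes, though above 0, was 0.13 (95% bootstrap interval 0.06 to 0.19). A candidate explanation that stays open and was not tested is the cassette itself, since in lines of this kind the inducible gene is placed beside Hprt on the X chromosome. Fam122b is the 11th annotated gene on its side, so transcription over a shorter distance is not excluded.

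Several motor neuron genes fell along with pan-neuronal genes. A lower share of neurons alone would lower both alike only if both were equally confined to neurons, which was not measured. The 15 motor neuron genes that fell were compared with the 13 pan-neuronal genes that fell. Their mean log2 level relative to the latter changed by -0.51 (pooled SD 0.054, 95% bootstrap interval over genes -0.81 to -0.23). Both sets were chosen because their genes fell in these same libraries, so this value cannot decide whether a lower share of neurons was the only change. The comparison is the third version of the test and was set after the others were seen. Relative to all 20 pan-neuronal genes, 5 panel genes gave -1.05 (pooled SD 0.12). All 34 listed members, which go both ways, gave 0.22 (pooled SD 0.064) on that scale. The versions differ in sign, so a lower share of neurons, as the only change or as a part of it, stays open. Another mixture of neuron types may contribute and cannot be told apart here from lower expression within motor neurons: among lists of other neurons with at least 5 listed members the V2 list, less 1 member not reported here, had the highest median, 0.55, but was not called by camera with all libraries, while the medians were -0.13 for dorsal interneuron and -0.19 for neural crest and sensory markers. An effect of the induced factor, the biological difference in the design, and one of doxycycline itself stay open and untested, because no culture without the inducible gene received doxycycline in these libraries.

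Glycolysis genes had higher values with doxycycline, with a median of 0.34. A lower level in library 1 could account for much of this, since the mean log2 level of the list was 10.8 in library 1, 11.3 in library 7, 11.3 in library 2 and 11.5 in library 8. Without library 1 the median was 0.10 and limma's camera gave an adjusted p of 0.0435, but libraries 8 and 7 alone differed by 0.21, so the part of library 1 cannot be told apart from that of doxycycline. An action of doxycycline on mitochondria through the integrated stress response was not decided either: the median of the stress response targets was 0.098 with all libraries (95% bootstrap interval of its difference from the glycolysis list -0.43 to -0.09), but 0.14 without library 1, above the 0.10 of the glycolysis list. An effect of the induced factor on this list stays open and was not tested.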
